A study of Homo sapiens with 12 samples.

How the data were processed

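The series holds RNA-seq of 12 libraries, 3 shCBX7 and 3 sh control in each of the human lines 5637 and 786-O. Cells were grown in RPMI-1640, RNA was taken with a column kit and libraries were made with the NEBNext Ultra Directional kit, per the labels' protocols. The authors deposited FPKM values, 1 per gene and library, in a separate table for each line, per the file headers. The aligner and counter are not given in the sources used here, and neither is the setting for strand. The submitters' processing notes name the mouse build mm10, although the samples are human. All 58735 gene identifiers of the 786-O table match GENCODE release 29 (GRCh38) in chromosome, start and end, so coordinates are given for that build. The table of 5637 holds 29890 gene symbols without identifiers or lengths. By symbol, 29809 of them (99.7%) could be matched to the 786-O table, and their positions are those of the matched gene.

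Each sample was placed in its group by its title and its cell line and genotype labels. The titles of 2 control libraries of 5637 carry another number, but their cell line label is 5637. The columns of the control libraries in the 5637 table could be tied to the group but not to a single sample, so they carry only the number in the table. Columns left without a group numbered 0. No 2 libraries of a line held identical values (15 pairs compared per line).

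Low FPKM values are whole multiples of what 1 read is worth, so reads could be recovered (tolerance 0.01). All 58735 genes came out whole in 786-O and 28078 of 29890 (93.9%) in 5637, where gene lengths came from the other table. The recovered reads in listed genes came to 17772719 to 29353270 per library in 5637 and 16384151 to 18868874 in 786-O. They served for depth and for an alternative test only. FPKM are not counts, so the main test was run on the log scale.

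Values were turned into log2(FPKM + 1), and genes with a mean FPKM of at least 0.5 over the 6 libraries of a line were tested with limma 3.58.1 (lmFit and eBayes with a mean-variance trend, R 4.3.3), shCBX7 minus control, within each line. P-values were adjusted after Benjamini and Hochberg, and genes under 0.05 were called. CBX7, FGFR3 and EZH2 were also compared by an exact two-sided permutation test, whose smallest p is 0.1. The difference between lines was the interaction term of a limma fit over all 12 libraries, for genes with a mean FPKM of at least 0.5 over all 12. Calls shared by both lines were compared with Fisher's exact test per direction. For 29 gene lists fixed before the data were examined, camera was run with a preset correlation of 0.01 and again with an estimated correlation, and fry as another alternative. Lists with under 3 tested members were not tested: endothelial markers in both lines, and renal tubule markers, histone genes and mitochondrial messages in 5637. Of the endothelial markers, ESAM was the tested member in 5637, where it was lower (log2 change -0.265).

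Genes named in the text followed a rule set before the data were examined. It takes CBX7, FGFR3 and EZH2, and the 10 genes with the largest rise and the 10 with the largest fall per line among called genes with a mean of at least 1 FPKM, arms that do not overlap and a symbol without a prefix of clones, bare identifiers or some non-coding RNAs. The prefixes left out include AL, so named genes such as ALDOA could not be picked for their rise or fall. It adds up to 4 members with the smallest p of each list that passed and 10 genes called in both lines. Other list members named beside their list's count, the FGF, PRC1, PRC2 and MAPK members in 5637 for example, were chosen after their values were seen. Some genes that the rule picked are not reported here.

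The alternatives were a pseudocount of 0.1, no filter on low values, quantile normalization, median centring, no mean-variance trend, each library left out in turn and the replicate number as a block. A voom fit on the recovered reads was added after the data were seen. It called 7248 of 13220 genes in 786-O and 5791 of 11618 in 5637. The count tests named for tables of raw counts were not run, because the tables hold none.

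The tests were tested on simulated data with known answers. Reads were drawn for the real genes at the real depths with 50 changed genes per fold size and line, at a dispersion estimated from the libraries (3.91e-04 in 5637, 0.00375 in 786-O). In the 5637 simulation (11802 genes) the limma test recovered 82% of genes changed 1.25-fold, 92% at 1.5-fold, 100% at 2-fold and 98% at 4-fold. In the 786-O simulation (13142 genes) it recovered 8%, 74%, 92% and 98%, and for the difference between lines (11838 genes) 31.7%, 95%, 100% and 97.6%. Unchanged genes made up 6.1%, 4.2% and 8.8% of the calls. Few genes were changed in the simulation, while in the real data 5651 of 12689 were called in 5637 and 6736 of 13220 in 786-O. The adjusted p depends on the share of changed genes, so the shares recovered need not hold for the real data. The first simulation used a dispersion estimate that was biased low, and it was replaced after its output was seen. The dispersion of 5637 is still low, so the shares recovered there hold only for a spread as small as that between these libraries. A search for short sequence words, used in the closing part, was tested on changes shuffled over genes. The genes that carry a drawn word, 1 of those that many genes carry, were then shifted down by 0.1 on the log2 scale. That word came first in 20 of 20 trials in each line. Without a shift the lowest z was -5.22 in 5637, where the real search ran from -5.55 to 6.89. Shuffling removes any link between sequence content and change, so the trials do not give the real background.

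Sequences for that search were 3' untranslated regions of at least 50 bases from GENCODE release 29, 1 transcript per protein-coding gene. Figures were drawn with matplotlib 3.10.9, and tests in Python 3.11.15 used numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.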

Results

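RNA-seq measured gene expression in 12 libraries from 2 human cancer cell lines, 5637 (bladder carcinoma) and 786-O (clear cell renal carcinoma). In each line, 3 libraries came from cells with CBX7 silenced (shCBX7) and 3 from control cells (sh control). CBX7 encodes a chromobox subunit of Polycomb repressive complex 1 (PRC1), a complex that keeps target genes silent. The question set by the series is what changes when CBX7 is lowered in each line, and its title places CBX7 beside EZH2, FGFR3 and cisplatin sensitivity. Values were FPKM (fragments per kilobase of gene, scaled by a total per library), in a table of 29890 genes for 5637 and a table of 58735 genes for 786-O. The totals implied by the values came to 19784641 to 32544606 per library in 5637 and 16503790 to 18966972 in 786-O. In 786-O they need not be read totals. There the total of control library 1, 16693519, lay below its 16961808 reads recovered in listed genes. Library values on the log scale correlated at 0.995 to 0.996 within an arm and 0.989 to 0.991 between arms in 5637. The 786-O libraries correlated at 0.991 to 0.993 within an arm and 0.964 to 0.965 between arms. The titles of 2 of the 3 control libraries of 5637 carry a number other than 5637, while their cell line label says 5637, and the table columns name the arms as si rather than sh. Nothing in the sources says that the libraries of an arm came from separate cultures, so the p-values measure only the spread between these libraries, which may be technical. All fold changes on the log scale are of log2(FPKM + 1), which understates the change of genes with low values.

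CBX7 was lower in the silenced arm of both lines, in every library. In 5637 its level was 1.86, 1.80 and 1.97 FPKM in the shCBX7 libraries and 2.19, 2.17 and 2.42 FPKM in the control libraries, so that 83.3% of the control mean remained. In 786-O it was 1.01, 0.892 and 1.07 FPKM against 1.63, 1.75 and 1.49 FPKM, which left 61.0%. The limma log2 change was -0.18 (SE 0.046, adjusted p = 0.0188) in 5637 and -0.40 (SE 0.076, adjusted p = 0.00364) in 786-O. An exact two-sided permutation test gave p = 0.1 in each line, the smallest value that 3 against 3 libraries allow. The call in 5637 was lost without the shCBX7 library numbered 2 (-0.16, limma adjusted p = 0.0606) or without the control library numbered 3 in the table (-0.14, limma adjusted p = 0.0586). These levels rest on 275 to 549 reads per library in 5637 and 111 to 240 in 786-O. CBX7 lies on chromosome 22 from 39120167 to 39152674, on the minus strand (GRCh38, GENCODE release 29).

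FGFR3, a receptor tyrosine kinase that is often activated in bladder cancer, was the called gene with the largest rise in 5637 on the log2(FPKM + 1) scale. It went from 2.15 ± 0.13 FPKM (SD, n = 3) in control cells to 16.3 ± 0.55 FPKM (SD, n = 3) after silencing, 7.59 times the control level. Its limma log2 change was 2.46 (SE 0.039, adjusted p = 7.27e-07). In 786-O, FGFR3 was 0.945 ± 0.226 FPKM (SD, n = 3) in control cells and 1.40 ± 0.17 FPKM (SD, n = 3) after silencing, a limma log2 change of 0.31 (SE 0.106, adjusted p = 0.0431). That call in 786-O was lost when any of 4 libraries was left out, with quantile normalization (limma adjusted p = 0.0589) and without the filter on low values (limma adjusted p = 0.123). EZH2, the methyltransferase of Polycomb repressive complex 2 (PRC2), fell in 5637 from 39.5 ± 0.62 to 30.3 ± 0.89 FPKM (SD, n = 3 each), a limma log2 change of -0.375 (SE 0.026, adjusted p = 1.09e-04). In 786-O it was 10.3 ± 0.92 FPKM in control cells and 9.25 ± 0.22 FPKM after silencing (SD, n = 3 each), which did not pass the test (log2 change -0.14, limma adjusted p = 0.124). It passed there only when the control library numbered 1 was left out (-0.21, limma adjusted p = 0.0102). The exact two-sided permutation p was 0.1 for FGFR3 in both lines and for EZH2 in 5637, and 0.2 for EZH2 in 786-O. FGFR3 lies on chromosome 4 from 1793293 to 1808872 (plus strand) and EZH2 on chromosome 7 from 148807383 to 148884321 (minus strand).

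**Figure D1:**
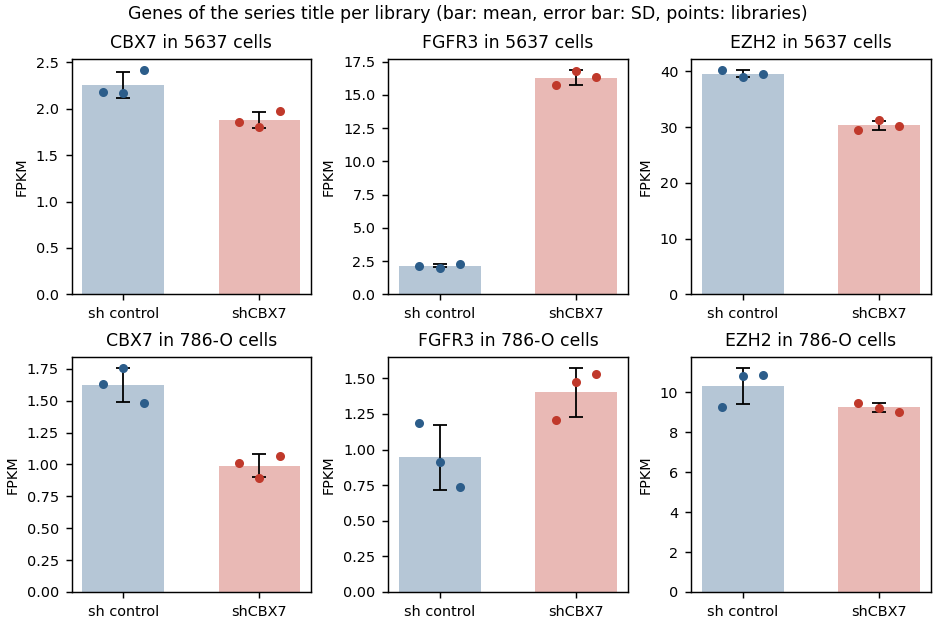
FPKM of CBX7, FGFR3 and EZH2 in each library of 5637 (top row) and 786-O (bottom row), with bars for the mean of 3 libraries and error bars for the SD. FGFR3 in 5637 sits between 15.7 and 16.8 FPKM in the shCBX7 libraries and between 2.02 and 2.27 FPKM in the control libraries.

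In 5637 cells the largest rises after silencing of CBX7, beside FGFR3, included IVL, TAGLN, HMOX1, HSPA6, FGFBP1, EDN1 and HRAS. IVL, a precursor of the cornified envelope, rose from 1.23 ± 0.11 to 5.67 ± 0.29 FPKM. TAGLN, the actin-binding protein transgelin, went from 0.550 ± 0.069 to 3.19 ± 0.11 FPKM. HMOX1, heme oxygenase, rose from 9.11 ± 0.30 to 25.7 ± 0.82 FPKM, and the heat shock gene HSPA6 from 18.0 ± 0.42 to 45.0 ± 1.43 FPKM. FGFBP1, a carrier protein that releases FGF ligands, rose from 3.28 ± 0.28 to 8.07 ± 0.57 FPKM, and EDN1, endothelin 1, from 3.04 ± 0.15 to 7.22 ± 0.36 FPKM (all SD, n = 3). The small GTPase HRAS went from 4.34 ± 2.0 to 17.8 ± 4.68 FPKM (SD, n = 3), with 1 control library at 2.03 FPKM and the others at 5.58 and 5.42 FPKM. Limma adjusted p-values of these genes ran from 2.43e-06 for HMOX1 to 0.00311 for HRAS. The vault RNA VTRNA1-2 also rose (0.539 to 4.32 FPKM, 8.02 times the control level, limma adjusted p = 0.00741), from libraries with as few as 0 reads.

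Among the genes that fell in 5637, the circadian gene PER1 went from 6.55 ± 0.16 to 3.28 ± 0.03 FPKM (limma adjusted p = 9.62e-06). SLURP1, a secreted protein of squamous epithelium, fell from 2.95 ± 0.46 to 1.27 ± 0.16 FPKM (limma adjusted p = 7.30e-04). The other 8 genes that the naming rule picked for their falls, which leaves out microRNA and small nucleolar RNA genes, were pseudogenes of small RNAs or of a ribosomal protein, namely RNU6-890P, RNU6-574P, RNY1P4, RPS3AP3, RNU7-49P, RNU6-658P, RNU6-807P and RN7SL809P. Their log2 changes ran from -1.19 for RNU6-890P to -0.74 for RN7SL809P, and libraries held as few as 0 reads of RNU6-574P and 1 read of RNU6-890P. RNU6-807P lost its call in 8 alternatives (without the low-value filter, limma adjusted p = 0.104) and RNU6-658P in 2 (0.0575 there). Reads of such pseudogenes can belong to other copies, so these values are uncertain. In all, 5651 of 12689 tested genes passed limma's adjusted p of 0.05 in 5637, 3094 higher and 2557 lower. Which side was larger depended on the scaling, with 2767 higher and 2885 lower after median centring and 2815 and 2840 after quantile normalization. Only 25 of them changed at least 2-fold on the log2(FPKM + 1) scale, 13 up and 12 down, and the median absolute log2 change over all tested genes was 0.10. With a pseudocount of 0.1 the number was 69 (27 up, 42 down), and with voom on recovered reads 66 (24 up, 42 down). The 2 arms did not overlap in 56.4% of tested genes, where chance gives 10%.

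Of the gene lists fixed before the data were examined, 8 passed in 5637 with camera at a preset correlation, and none of the 8 passed with an estimated correlation. Basal urothelial markers, keratins and adhesion proteins of the basal layer, rose in 14 of 21 members and fell in 3 (14 and 4 adjusted over the list alone, camera adjusted p = 0.0114). KRT5 rose from 189 ± 1.8 to 265 ± 2.1 FPKM, KRT17 from 209 ± 2.2 to 313 ± 3.4 FPKM, KRT6A from 99 ± 2.4 to 142 ± 4.5 FPKM and KRT6B from 0.709 ± 0.122 to 2.31 ± 0.15 FPKM (SD, n = 3). KRT16, CD44 and ITGB4 were the members that fell, and with an estimated correlation the list had an adjusted p = 0.287. Keratins 5, 6A, 6B, 14, 16 and 17 share long stretches of sequence, so their separate values are less certain.

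NF-kB targets and cytokines rose in 14 of 25 members and fell in 3 in 5637 (15 and 3 adjusted over the list alone, camera adjusted p = 0.00381). The neutrophil chemokines CXCL1 (25.5 ± 0.7 to 51.2 ± 1.1 FPKM) and CXCL2 (4.81 ± 0.48 to 12.2 ± 0.3 FPKM) were among them. The colony-stimulating factors CSF2 (11.4 ± 0.3 to 20.6 ± 0.8 FPKM) and CSF3 (6.24 ± 0.34 to 11.5 ± 0.3 FPKM) rose as well (SD, n = 3). With an estimated correlation this list had an adjusted p = 0.282. Genes of the integrated stress response, which follows phosphorylation of the translation initiation factor eIF2, rose in 14 of 27 members and fell in 4 (14 and 4 adjusted over the list alone, camera adjusted p = 0.00864). TRIB3, a pseudokinase induced by stress, rose from 8.45 ± 0.08 to 15.8 ± 0.2 FPKM and PSAT1, an enzyme of serine synthesis, from 11.9 ± 0.7 to 18.1 ± 0.5 FPKM. The amino acid transporter SLC7A5 (272 to 333 FPKM) and the carboxykinase PCK2 (8.13 to 10.5 FPKM) rose too, and with an estimated correlation the list had an adjusted p = 0.287.

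Mitotic genes fell in 5637: 17 of 31 G2/M and mitosis genes were lower and 1 higher (17 and 1 adjusted over the list alone, camera adjusted p = 9.87e-05). The kinase NEK2 fell from 29.1 ± 0.7 to 23.2 ± 0.2 FPKM, the phosphatase CDC25B from 124 ± 3 to 99.7 ± 1.2 FPKM, TOP2A from 281 ± 4 to 244 ± 2 FPKM and CDC20 from 57.3 ± 0.6 to 48.4 ± 1.5 FPKM (SD, n = 3). The median member changed by -0.10, and with an estimated correlation the list had an adjusted p = 0.282. CDK inhibitors, which brake the cell cycle, fell in 7 of 8 members (8 adjusted over the list alone, camera adjusted p = 4.80e-04, or an adjusted p = 0.287 with an estimated correlation). CDKN2A went from 75.5 ± 1.0 to 64.9 ± 1.2 FPKM and CDKN2B, next to it on chromosome 9, from 16.4 ± 0.9 to 12.3 ± 0.6 FPKM. CDKN1B (29.7 to 25.1 FPKM) and CDKN2D (28.6 to 21 FPKM) were lower too.

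HOX genes, which pattern the body axis and are classic Polycomb targets, fell in 16 of 29 members and rose in 3 in 5637 (16 and 3 adjusted over the list alone, camera adjusted p = 0.00306). HOXA9 went from 39.5 ± 1.3 to 31.6 ± 0.9 FPKM, HOXA2 from 7.69 ± 0.47 to 5.32 ± 0.31 FPKM, HOXB6 from 8.26 ± 0.26 to 6.67 ± 0.19 FPKM and HOXA3 from 12 ± 0.3 to 9.75 ± 0.43 FPKM (SD, n = 3). HOXD13, HOXA6 and HOXB13 rose, and with an estimated correlation the list had an adjusted p = 0.287. Cholesterol synthesis genes fell in 10 of 23 members and rose in 1 (10 and 1 adjusted over the list alone, camera adjusted p = 0.0128, or an adjusted p = 0.282 with an estimated correlation). STARD4 (8.30 to 5.87 FPKM), MSMO1 (32.8 to 25.3 FPKM), INSIG1 (32.7 to 24.9 FPKM) and the transcription factor SREBF2 (39.2 to 34.6 FPKM) were lower. Cytosolic ribosomal protein genes fell in 12 of 43 members and rose in 0 (10 and 0 adjusted over the list alone, camera adjusted p = 3.00e-04, or an adjusted p = 0.438 with an estimated correlation). RPL4, RPL3 and RPS24 had log2 changes of -0.12, -0.11 and -0.11, and with quantile normalization the calls of RPL4 (limma adjusted p = 0.199) and RPL3 (limma adjusted p = 0.261) were lost.

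Of the 25 lists tested in 5637, 17 did not pass. Targets of p53 were lower in 10 of 23 members and higher in 4 (12 and 6 adjusted over the list alone, camera adjusted p = 0.0557). Apoptosis regulators were lower in 11 and higher in 4 of 27 (12 and 4 adjusted over the list alone, 0.0702). PRC2 subunits were lower in 4 of 10, EZH1, EZH2, MTF2 and RBBP4, and higher in SUZ12 (5 and 1 adjusted over the list alone, 0.0782). PRC1 subunits were higher in 6 and lower in 7 of 17 (6 and 7 adjusted over the list alone, 0.800), with KDM2B and PCGF6 among the first and RYBP and PCGF1 among the second. FGF receptors, ligands and adaptors were higher in 4 and lower in 1 of 15 (4 and 0 adjusted over the list alone, 0.341). Beside FGFR3 and FGFBP1 those were FGFRL1 and SHC1. MAPK pathway output genes were higher in 7 and lower in 3 of 18 (7 and 3 adjusted over the list alone, 0.225), among them FOSL1, CCND1 and MYC on the higher side. Genes of cisplatin transport and detoxification were higher in 6 and lower in 2 of 17 (6 and 2 adjusted over the list alone, 0.558). Repair genes of nucleotide excision and crosslinks were higher in 10 and lower in 10 of 34 (15 and 10 adjusted over the list alone, 0.800).

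Lists of the cell state stayed under the threshold in 5637 as well. Luminal urothelial markers were higher in 5 and lower in 3 of 14 (5 and 3 adjusted over the list alone, camera adjusted p = 0.985), and epithelial adhesion genes higher in 5 and lower in 7 of 20 (5 and 7 adjusted over the list alone, 0.333). Mesenchymal and matrix genes were higher in 5 and lower in 7 of 18 (5 and 9 adjusted over the list alone, 0.592), with a median of -0.08, a mean of 0.06 and a test on the lower side. TGF-beta targets were higher in 8 and lower in 7 of 21 (8 and 7 adjusted over the list alone, 0.800), and HIF targets higher in 6 and lower in 9 of 26 (6 and 10 adjusted over the list alone, 0.463). Interferon response genes were higher in 3 and lower in 5 of 29 (3 and 4 adjusted over the list alone, 0.377). G1/S and replication genes were higher in 8 and lower in 7 of 33 (8 and 7 adjusted over the list alone, 0.999), with a median and mean just above 0 and a test on the lower side. Nuclear genes of oxidative phosphorylation were higher in 2 and lower in 4 of 31 (2 and 2 adjusted over the list alone, 0.592), with a median above 0 and a mean below it. Leukocyte markers had 3 tested members, of which CORO1A was higher, LAPTM5 lower and CD14 not called (1 and 1 adjusted over the list alone, 0.999), with a median and mean above 0 and a test on the lower side.

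In 786-O cells ACTA2 had the largest rise after silencing of CBX7, and ACTB and ACTG1 had the largest falls on the log2(FPKM + 1) scale. ACTB, which encodes beta-actin, fell from 1613 ± 25 to 166 ± 2.9 FPKM, and ACTG1, gamma-actin, from 1746 ± 62 to 189 ± 4.9 FPKM (SD, n = 3). ACTA2, smooth muscle alpha-actin, rose from 2.05 ± 0.19 to 89.7 ± 4.5 FPKM, 43.8 times the control level. Interferon response genes rose nearly throughout, while most listed genes of the ribosome, of DNA replication and of mitosis fell. The ribosomal list did not pass with an estimated correlation (adjusted p = 0.133). The limma log2 changes of ACTA2, ACTB and ACTG1 were 4.90 (SE 0.064), -3.27 (SE 0.040) and -3.20 (SE 0.046), with adjusted p-values of 3.51e-08, 3.51e-08 and 4.88e-08. ACTB lies on chromosome 7 from 5527147 to 5563784, ACTG1 on chromosome 17 from 81509971 to 81523847 and ACTA2 on chromosome 10 from 88935074 to 88991339, all on the minus strand. Actin genes and their pseudogenes share sequence, and the ACTA2 interval overlaps FAS on the opposite strand, so reads between these genes may be misassigned. ACTB and ACTG1 fell, so a constant share of their reads given to ACTA2 would have fallen too. This argues against ACTB and ACTG1 as the source of the ACTA2 rise. FAS itself rose from 9.17 ± 0.78 to 29.4 ± 1.1 FPKM.

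Other genes with large rises in 786-O included chemokines and antiviral genes. The monocyte chemokine CCL2 went from 10.7 ± 0.7 to 81.2 ± 3.4 FPKM and the T cell chemokine CXCL11 from 1.02 ± 0.16 to 10.3 ± 0.5 FPKM. IFITM1, an antiviral membrane protein, rose from 5.94 ± 1.34 to 81.1 ± 6.7 FPKM and OAS1, which senses double-stranded RNA, from 8.83 ± 0.79 to 51.1 ± 0.8 FPKM. EDN1 rose from 3.71 ± 0.03 to 27.8 ± 1.7 FPKM. CD69 (0.705 ± 0.145 to 10.8 ± 0.9 FPKM) and ARHGDIB (9.06 ± 0.57 to 61.5 ± 2.1 FPKM), both best known from leukocytes, rose too, as did SPOCD1 (3.16 to 24.7 FPKM) and NEURL3 (0.872 to 9.72 FPKM) (SD, n = 3). Of the leukocyte markers, PTPRC was listed at 0 in all libraries, LAPTM5 fell from 17.5 ± 1.9 to 8.07 ± 0.33 FPKM and CSF1R rose from 1.38 ± 0.10 to 3.16 ± 0.23 FPKM. Beside the actins, the largest falls on the log2(FPKM + 1) scale were in LGALS3BP (251 ± 15 to 36.0 ± 1.9 FPKM), SNRPC (177 ± 7 to 26.7 ± 2.4 FPKM) and HECTD3 (17.7 ± 1.9 to 2.57 ± 0.06 FPKM). PDLIM1 (208 to 39.8 FPKM), PSAP (430 to 84.1 FPKM), IDH2 (76.4 to 14.4 FPKM), B4GALT1 (26.5 to 4.74 FPKM) and the fatty acid desaturase SCD (112 to 22.7 FPKM) followed. Limma adjusted p-values of these 8 genes ran from 2.16e-07 for PDLIM1 to 1.40e-06 for B4GALT1. Genes lower by at least 2-fold in 786-O carried 1 short word of the CBX7 transcript more often than all genes searched (48.4% against 19.6%, closing part). Whether some of the falls in 786-O are off-target effects of the silencing RNA therefore stays open.

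**Figure D2:**
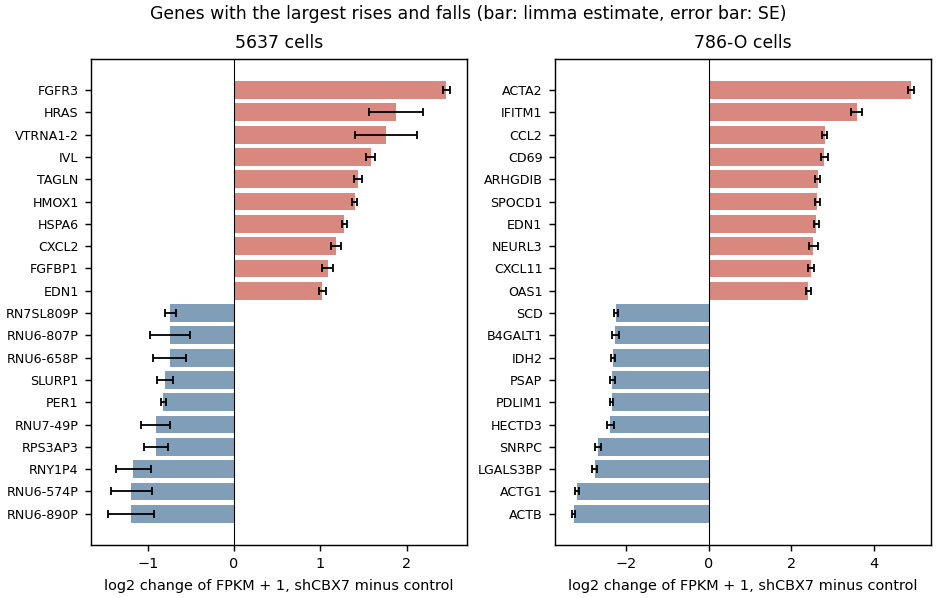
Limma log2 change of FPKM + 1 (shCBX7 minus control, 3 libraries per arm) for the 10 named genes with the largest rises and the 10 with the largest falls in each line, with error bars for the SE. The scale differs between the panels: the largest rise is 2.46 in 5637 (FGFR3) and 4.90 in 786-O (ACTA2).

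In all, 6736 of 13220 tested genes passed limma's adjusted p of 0.05 in 786-O, 3271 higher and 3465 lower (3364 and 3353 after median centring, 3086 and 3014 without the low-value filter). Of these, 464 changed at least 2-fold on the log2(FPKM + 1) scale, 273 up and 191 down. With a pseudocount of 0.1 the number was 915 (533 up, 382 down), and with voom on recovered reads 971 (581 up, 390 down). The arms did not overlap in 60.3% of tested genes, where chance gives 10%, and the median absolute log2 change was 0.24. Of 28 gene lists tested, 16 passed with camera at a preset correlation. With an estimated correlation 4 of them passed, the interferon response, NF-kB targets and cytokines, and both cell cycle lists.

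Interferon response genes rose in 34 of 36 members in 786-O and fell in 1 (34 and 1 adjusted over the list alone). The median member rose by 1.30 on the log2 scale (camera adjusted p = 1.41e-18, or an adjusted p = 0.0123 with an estimated correlation). IFI27 went from 21.1 ± 0.6 to 92.2 ± 2.8 FPKM, IFIT1 from 8.96 ± 0.29 to 36.5 ± 0.8 FPKM and IFIT3 from 23.3 ± 0.9 to 74.6 ± 1.7 FPKM (SD, n = 3). NF-kB targets and cytokines rose in 22 of 28 members and fell in 4 (22 and 4 adjusted over the list alone, camera adjusted p = 4.18e-07, or an adjusted p = 0.0364 with an estimated correlation). The adhesion receptor ICAM1 rose from 53.6 ± 1.4 to 127 ± 4 FPKM, CXCL2 from 10.4 ± 0.5 to 32.7 ± 2.3 FPKM and the feedback inhibitor TNFAIP3 from 13.2 ± 0.6 to 31.5 ± 0.8 FPKM. CXCL5, LIF, NFKB1 and TNFAIP2 were the members that fell.

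Proliferation genes fell in 786-O. G1/S and replication genes were lower in 27 of 33 members and higher in 0 (27 and 0 adjusted over the list alone, camera adjusted p = 4.21e-08, or an adjusted p = 0.0364 with an estimated correlation). The helicase subunits MCM6 (24.5 ± 0.7 to 11.4 ± 0.3 FPKM), MCM4 (50 ± 1.5 to 29.5 ± 0.7 FPKM) and MCM7 (117 ± 6 to 75.7 ± 1.8 FPKM) fell, and thymidine kinase TK1 went from 181 ± 17 to 61.0 ± 2.2 FPKM. G2/M and mitosis genes were lower in 25 of 31 members and higher in 0 (28 and 0 adjusted over the list alone, camera adjusted p = 2.47e-08, or an adjusted p = 0.0481 with an estimated correlation). CCNB1 fell from 69.6 ± 1.0 to 40.5 ± 1.7 FPKM, CCNB2 from 46.4 ± 1.6 to 24.7 ± 1.2 FPKM, CDC20 from 257 ± 15 to 139 ± 4 FPKM and PLK1 from 43.5 ± 2.6 to 22.8 ± 1.0 FPKM (SD, n = 3). The CDK inhibitor CDKN1A rose from 46.2 ± 4.5 to 139 ± 3 FPKM, while CDK inhibitors as a list were higher in 3 and lower in 3 of 6 (3 and 3 adjusted over the list alone, camera adjusted p = 0.582).

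Cytosolic ribosomal protein genes fell in 42 of 44 members in 786-O and rose in 0 (43 and 0 adjusted over the list alone, camera adjusted p = 1.32e-16). With an estimated correlation the list had an adjusted p = 0.133. RPL4 went from 295 ± 4 to 132 ± 4 FPKM, RPL3 from 404 ± 12 to 194 ± 1 FPKM and RPL14 from 114 ± 2 to 52.8 ± 3.3 FPKM (SD, n = 3). Ribosomal protein genes have many processed pseudogenes, so part of their reads may be counted elsewhere. Nuclear genes of oxidative phosphorylation fell in 22 of 34 members and rose in 2 (22 and 2 adjusted over the list alone, camera adjusted p = 5.08e-05, or an adjusted p = 0.248 with an estimated correlation). SDHD, a subunit of complex II, fell from 21.8 ± 0.2 to 5.89 ± 0.42 FPKM, and the ATP synthase subunits ATP5F1B (414 to 239 FPKM) and ATP5F1A (37.8 to 23.5 FPKM) fell. Cholesterol synthesis genes fell in 16 of 23 members and rose in 2 (16 and 3 adjusted over the list alone, camera adjusted p = 2.14e-04, or an adjusted p = 0.0689 with an estimated correlation). DHCR7 (50 to 22 FPKM), MSMO1 (42.3 to 25.3 FPKM) and ACAT2 (27.6 to 16.6 FPKM) fell, and INSIG1, which holds back the sterol sensor, rose (41.3 to 76.1 FPKM).

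Stress and death genes mostly rose in 786-O. The integrated stress response was higher in 19 and lower in 3 of 28 members (20 and 3 adjusted over the list alone, camera adjusted p = 1.32e-05, or an adjusted p = 0.12 with an estimated correlation). DDIT3 rose from 19.3 ± 1.0 to 56.0 ± 2.2 FPKM, NUPR1 from 15 ± 1.1 to 44.5 ± 2.3 FPKM, PPP1R15A from 26.8 ± 1.5 to 62.0 ± 1.5 FPKM and STC2 from 42.0 ± 1.2 to 75.9 ± 2.6 FPKM (SD, n = 3). Targets of p53 were higher in 11 and lower in 5 of 21 (11 and 5 adjusted over the list alone, camera adjusted p = 0.0259, or an adjusted p = 0.353 with an estimated correlation). Beside FAS and CDKN1A, the death receptor TNFRSF10B (32.0 to 55.7 FPKM) and GDF15 (39.6 to 112 FPKM) rose. Apoptosis regulators were higher in 14 and lower in 2 of 25 (15 and 3 adjusted over the list alone, camera adjusted p = 0.00424, or an adjusted p = 0.0967 with an estimated correlation). The pro-death factor PMAIP1 (54.8 to 114 FPKM) rose, as did the survival factor BCL2A1 (7.29 to 22.9 FPKM), while the survival factor BCL2L1 fell (50.3 to 23.7 FPKM).

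Mesenchymal and matrix genes rose in 14 and fell in 3 of 20 members in 786-O (14 and 3 adjusted over the list alone, camera adjusted p = 5.18e-04, or an adjusted p = 0.0689 with an estimated correlation). Beside ACTA2, the matrix protein TNC rose from 11.8 ± 0.3 to 31.9 ± 1.1 FPKM, and the integrin ITGA5 from 50.2 ± 1.2 to 111.2 ± 0.3 FPKM (SD, n = 3). TGF-beta targets rose in 12 and fell in 2 of 22 (13 and 2 adjusted over the list alone, camera adjusted p = 0.00972, or an adjusted p = 0.117 with an estimated correlation), with COL4A1 (11.8 to 22.6 FPKM) and TGFBR2 (45.1 to 68.2 FPKM) higher and ID1 (171 to 99.9 FPKM) lower. MAPK pathway output genes rose in 11 and fell in 5 of 19 (11 and 5 adjusted over the list alone, camera adjusted p = 0.0381, or an adjusted p = 0.300 with an estimated correlation). The phosphatases DUSP5 (67.0 to 150 FPKM) and DUSP6 (5.67 to 12.1 FPKM) and the early response gene IER3 (270 to 541 FPKM) rose, and EGR1 fell (2.96 to 0.285 FPKM). HOX genes rose in 10 and fell in 3 of 28 (10 and 3 adjusted over the list alone, camera adjusted p = 0.0238, or an adjusted p = 0.194 with an estimated correlation). HOXA9 (20 to 38.1 FPKM), HOXB7 (18.2 to 36.0 FPKM) and HOXC6 (1.73 to 3.86 FPKM) rose and HOXA3 fell (10.5 to 5.65 FPKM).

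Lists tied to cisplatin fell in 786-O at the preset correlation. Genes of cisplatin transport and detoxification were lower in 8 and higher in 1 of 19 (8 and 1 adjusted over the list alone, camera adjusted p = 0.0190, or an adjusted p = 0.237 with an estimated correlation). The glutathione enzymes GSR (23.7 ± 0.8 to 12.7 ± 0.7 FPKM), GSS (21.4 ± 1.5 to 12.1 ± 0.3 FPKM) and GCLM (23.9 ± 0.7 to 16.3 ± 1.0 FPKM) fell, and the metallothionein MT1X rose (7.59 ± 0.76 to 12.4 ± 1.3 FPKM) (SD, n = 3). Repair genes of nucleotide excision and crosslinks were lower in 12 and higher in 1 of 31 (12 and 1 adjusted over the list alone, camera adjusted p = 0.0259, or an adjusted p = 0.300 with an estimated correlation). DDB1 (18.9 to 9.05 FPKM) and the Fanconi anaemia genes FANCG (21.9 to 10.5 FPKM), FANCA (3.34 to 1.74 FPKM) and FANCE (6.15 to 2.83 FPKM) were lower.

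The remaining lists did not pass in 786-O. PRC1 subunits were higher in 6 and lower in 3 of 18 (7 and 3 adjusted over the list alone, camera adjusted p = 0.340), with CBX2 and CBX8 higher and CBX6 lower. PRC2 subunits were higher in 5 and lower in 3 of 11 (5 and 3 adjusted over the list alone, 0.403). FGF receptors, ligands and adaptors were higher in 5 and lower in 5 of 14 (5 and 5 adjusted over the list alone, 0.927), with FGF1 higher, FGFR4 lower, a median below 0 and a mean above it. Renal tubule markers were higher in 3 and lower in 5 of 10 (4 and 6 adjusted over the list alone, 0.402), with CDH6 and PAX8 among the lower. HIF targets were higher in 10 and lower in 7 of 24 (10 and 7 adjusted over the list alone, 0.340). Luminal urothelial markers were higher in 5 and lower in 1 of 10 (6 and 2 adjusted over the list alone, 0.191), basal ones higher in 3 and lower in 2 of 5 (3 and 2 adjusted over the list alone, 0.336), and epithelial adhesion genes higher in 3 and lower in 1 of 7 (3 and 1 adjusted over the list alone, 0.269). Histone genes of the replication-dependent type were higher in 4 and lower in 1 of 7 (4 and 1 adjusted over the list alone, 0.264), and messages of the mitochondrial genome lower in 3 and higher in 0 of 13 (2 and 0 adjusted over the list alone, 0.378). Leukocyte markers were higher in 1, CSF1R, and lower in 1, LAPTM5, of 4 (1 and 2 adjusted over the list alone, 0.616).

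**Figure D3:**
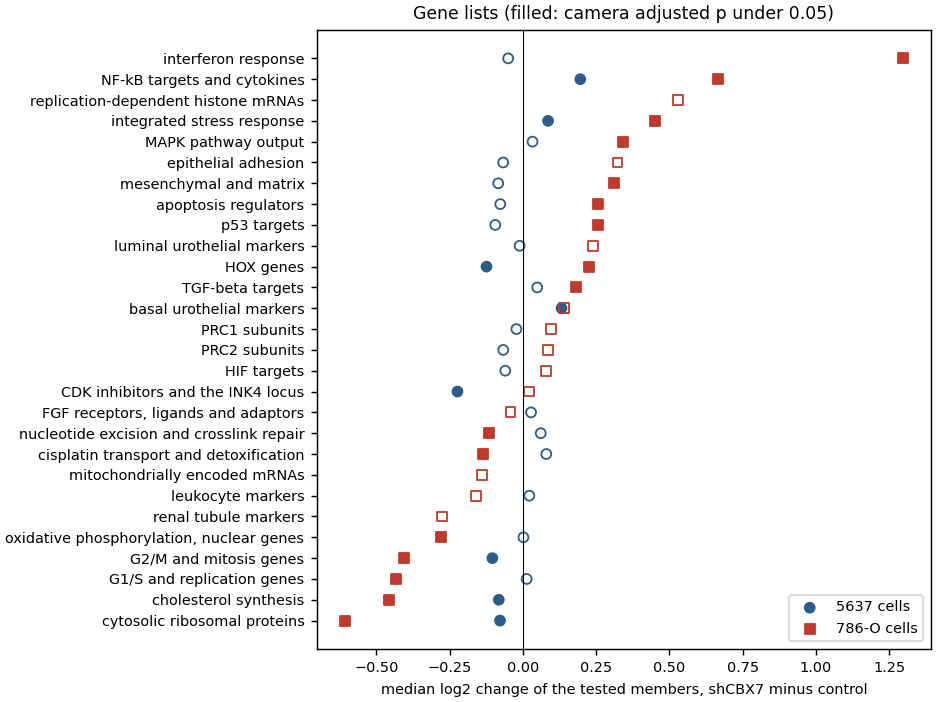
Median log2 change of FPKM + 1 (shCBX7 minus control) of the tested members of each gene list, circles for 5637 and squares for 786-O, filled where the camera adjusted p with the preset correlation is under 0.05. Medians run from -0.22 to 0.20 in 5637 and from -0.61 (cytosolic ribosomal proteins) to 1.30 (interferon response) in 786-O.

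Genes that rose in both lines included regulators of the actin cytoskeleton and secreted inflammatory factors. TPM4, a tropomyosin, rose from 51.0 ± 0.5 to 97.7 ± 1.6 FPKM in 5637 and from 48.3 ± 1.4 to 243 ± 8 FPKM in 786-O. CALD1, the actin-binding caldesmon, rose from 10.7 ± 0.2 to 19 ± 0.2 FPKM in 5637 and from 14.7 ± 0.7 to 39.8 ± 0.9 FPKM in 786-O. The actin bundler PLS3 (47.7 to 69.4 FPKM and 58.0 to 116.1 FPKM) and the membrane linker MSN (24.2 to 34.3 FPKM and 189 to 340.4 FPKM) rose in 5637 and 786-O. CXCL1 went from 281 ± 13 to 547 ± 22 FPKM in 786-O, and CSF2 from 183 ± 14 to 386 ± 9 FPKM (SD, n = 3). The polyamine enzyme ODC1 rose from 16.7 to 31.2 FPKM in 5637 and from 38.7 to 59.6 FPKM in 786-O, and TNC from 151 to 202 FPKM in 5637. With EDN1 and HMOX1 (42.8 to 73.1 FPKM in 786-O), these were the 10 genes called in both lines with the smallest larger adjusted p, and all 10 rose in both.

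Over the 10354 genes tested in both lines, 871 were higher in both, where 711.1 would be shared by independent lists (odds ratio 1.49, Fisher's exact test p = 1.051e-15, BH-adjusted over 4 tests 4.204e-15). Lower in both were 648 genes against 595 (odds ratio 1.17, Fisher's exact test p = 0.00434, BH-adjusted 0.00869). Opposite calls numbered 779 (higher in 5637, lower in 786-O) against 817.6, and 487 against 517.4, with BH-adjusted Fisher p-values of 0.0815 and 0.0886. Without the low-value filter both were above chance, 584 against 428.3 (Fisher's exact test p = 5.996e-18) and 364 against 323.1 (p = 0.00900). The first was below chance with quantile normalization (701 against 749.4, Fisher's exact test p = 0.0162) and without the mean-variance trend (745 against 798, p = 0.00937). Across these genes, which are not independent replicates, log2 changes correlated at 0.12 (Pearson) and 0.086 (Spearman). The lines share no libraries.

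A limma interaction term over all 12 libraries called 6808 of 12777 genes, 3101 with a higher change in 786-O and 3707 with a lower one (3535 and 3345 after median centring). Genes entered this fit by their mean over all 12 libraries, while 10354 were tested in both lines. For a gene too low in 1 line to be tested there, a difference can reflect low expression in that line. FGFR3 rose more in 5637 by 2.15 on the log2 scale (difference -2.15, SE 0.11, limma adjusted p = 3.69e-08). CBX7 fell further in 786-O (difference -0.22, SE 0.075, limma adjusted p = 0.0268), and EZH2 fell further in 5637 (0.235, SE 0.073, limma adjusted p = 0.0176). TPM4, TNC and EDN1 rose more in 786-O and HMOX1 and ODC1 more in 5637, while the difference for CXCL1 did not pass (-0.02, SE 0.058, limma adjusted p = 0.797). ACTB (log2 change 0.10) and ACTA2 (0.06) were not called in 5637, and their differences between the lines passed (limma adjusted p = 5.08e-12 each). Of 26 lists compared, the change of 16 differed between the lines with camera at the preset correlation, and of 9 with an estimated correlation, the interferon response first. Lists compared here can hold members too low in 5637 to be tested there (interferon response 37 members, against 29 tested in 5637). The tables were normalized separately, so only changes within a line, not levels, are compared.

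**Figure D4:**
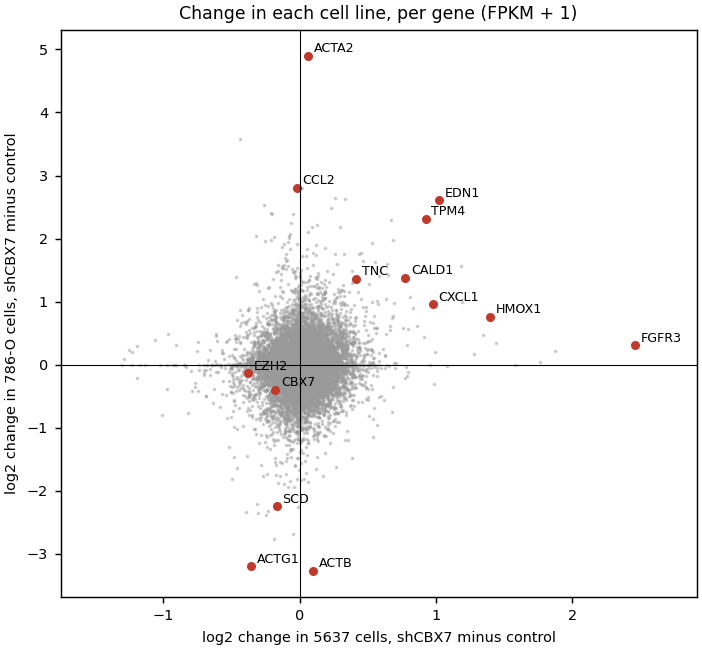
Log2 change of FPKM + 1 (shCBX7 minus control) of each gene in 5637 (horizontal axis) and 786-O (vertical axis), 1 point per gene, with named genes in red. FGFR3 lies far to the right at 2.46 and 0.31, and ACTB and ACTA2 lie near 0 on the horizontal axis at -3.27 and 4.90 on the vertical axis.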

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

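The genes and lists below stand out because their change after CBX7 silencing differed between the lines by a limma interaction test, and the rule that picked the genes was set after results were seen. It took CBX7, FGFR3, EZH2, the 10 genes that the naming rule picked as called in both lines, and the 10 others with the smallest interaction p. Other genes named in both lines were not taken. Among those, HOXA9 (-0.314 in 5637, 0.901 in 786-O) and INSIG1 (-0.381 and 0.864) changed in opposite directions. Differences are log2 changes in 786-O minus those in 5637. Of the title genes, CBX7 (-0.222), FGFR3 (-2.15) and EZH2 (0.235) differed. TPM4 (1.385), CALD1 (0.602), CSF2 (0.269), PLS3 (0.459), TNC (0.947), EDN1 (1.583) and MSN (0.364) rose more in 786-O, and ODC1 (-0.253) and HMOX1 (-0.642) rose more in 5637. The genes with the smallest p were ACTB (-3.372), ACTA2 (4.834), ACTG1 (-2.845), SCD (-2.083), PDLIM1 (-2.048), CCL2 (2.826), IDH2 (-2.101), LGALS3BP (-2.583), ARHGDIB (2.373) and PSAP (-1.946). CCL2 was too low in 5637 to be tested there, so its difference may reflect low expression in that line. With 3 libraries per arm, no test for a single far-off library was run.

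Of the 26 lists compared, 16 differed between the lines with camera at the preset correlation. Some held members too low in 5637 to be tested there, as the interferon response (37 members, 29 tested in 5637) and NF-kB targets (29 and 25) did. The interferon response (adjusted p = 7.71e-20), NF-kB targets (0.00126), mesenchymal genes (0.00107), apoptosis regulators (0.00339), HOX genes (0.00339) and TGF-beta targets (0.00654) had the higher change in 786-O. G1/S genes (2.98e-07), G2/M genes (3.13e-05) and cholesterol synthesis (0.00339) had the lower change there. These 9 lists also differed with an estimated correlation. The other 7 did not: ribosomal proteins (7.33e-13, or an adjusted p = 0.0918 with an estimated correlation), the integrated stress response (0.000948, or 0.119), p53 targets (0.00126, or 0.118) and oxidative phosphorylation (0.0103, or 0.221). The last 3 of them were nucleotide excision and crosslink repair (0.0179, or an adjusted p = 0.18 with an estimated correlation), CDK inhibitors (0.0214, or 0.188) and cisplatin transport (0.0214, or 0.112).

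For the fall of ACTB and ACTG1 in 786-O, the tests of scaling, of an effect shared by both lines and of sequence matches were chosen after the result was seen, and the bound for actin 3' UTR words replaced an earlier one that was not met. Other actin genes and pseudogenes gained only 2.7% of the reads lost, ACTB stayed at -3.26 after quantile normalization, the mean of both actins was -3.222 beside genes of like length and GC content, and in 5637 ACTB changed by 0.099 and ACTG1 by -0.355, which argues against shared reads, scaling, length bias and a fall of like size in both lines. Among 16262 words of 7 bases, CTCTGCT, which is in the CBX7 transcript, marked lower genes in 786-O most strongly (z = -13.77, highest z of any word 5.38, and z = -2.31 at rank 181 in 5637, where GAAAGGA was lowest at -5.55). The shift was small, with a median log2 change of -0.103 in the 2089 genes that carry the word (-0.1 with 1 site, -0.122 with 2 or more). Of genes lower by at least 2-fold, 48.4% carried it, against 19.6% of all genes searched and 11.2% of genes higher by at least 2-fold. Off-target silencing through a short match would give such a pattern, so for the lower genes as a set it stays open. However, 3137 of the words are in CBX7, and 0 of the CBX7 words that pass are in the 3' UTR of either actin. The 2 stretches of 19 bases of CBX7 closest to both actins, with at most 3 mismatches, carry CTCTGCT, but in CAAGGAGAAGCTCTGCTTC a mismatch to both actins falls inside the word, 28 other genes matched as closely had a median log2 change of -0.063, and the silencing RNA's sequence is not given in the sources used here, so an off-target effect on the actins and an effect of CBX7 loss in this line stay open.

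For the rise of FGFR3 in 5637, the tests of scaling and of proportion to the fall of CBX7 were chosen after the result was seen. The other FGF receptor genes together changed by 3.6 reads per 1e+06 while FGFR3 gained 68.64. These values use gene lengths from the 786-O table, with which FGFR3 in 5637 did not come out in whole reads. The 68.64 is therefore approximate, and the voom fit left FGFR3 out in 5637. FGFR3 stayed at 2.445 or above under other scalings, and the largest change among tested genes within 100000 bases was 0.349 (LETM1). Together these values argue against shared reads, scaling and read-through. CBX7 fell further in 786-O, yet FGFR3 rose less there (difference -2.15), which argues against a rise in proportion to the fall of CBX7 across the lines. Each line has a single silenced arm, so proportion within a line could not be tested. An effect of CBX7 loss that depends on the line and an off-target effect of the silencing RNA in 5637 stay open, since the sources used here do not say how many silencing RNAs were used.

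For the interferon response in 786-O, the tests of leukocytes and of scaling were chosen after the result was seen. PTPRC was listed at 0 FPKM in the silenced libraries and the median of the list was 1.314 after quantile normalization, which argues against leukocytes in the cultures and against scaling. IFNB1 reached 1.043 FPKM in a silenced library, with 0.5225 or more in each, and at most 0.0635 FPKM in control libraries, so interferon made by the cells stays open. A response to the silencing RNA itself and a response to loss of CBX7 both go with the arm, and no test here separates them.

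The library labels were also regrouped between arms, in all 10 splits within a line and in 100 drawn splits of both lines, a test chosen after the results were seen. In 5637 the real arms gave 5651 called genes and the highest other split 1, and in 786-O they gave 6736 and 0. Lists past the threshold numbered 8 against at most 4 in 5637 and 16 against at most 12 in 786-O. In each of these the real split was the only 1 as large, but 10 splits are too few for a share under 0.05. The other splits mix libraries of both arms, so the real difference adds to their spread or remains in part. Their counts are therefore not a chance level. Of the 100 splits of both lines, 1, the real arms, had as many genes changed in the same direction (1519). The highest other number, 1266, equals the count of opposite calls of the real arms, which is what mirroring a line gives, so it is not a chance level. For the difference between lines 2 of 100 were as large (6808, highest other 7055), and the other 1 is the real arms with a line mirrored.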

How the results depend on the processing

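Most results kept their direction and their side of the threshold. Called genes ranged from 4942 to 5791 in 5637 and 6100 to 7248 in 786-O over the alternatives, and from 4677 to 5128 and 5704 to 6747 with a library left out. The difference between lines ranged from 6434 to 6922, or 6247 to 7130 with a library left out, and the overlaps from 697 to 871 (higher) and 487 to 725 (lower). Beside CBX7, FGFR3 and EZH2, none of 88 named genes in 786-O lost a call, and of 56 in 5637, 4 did in 12 of 724 values. With a library left out, CBX7 ranged from -0.2 to -0.142 in 5637 (not called at -0.158 and -0.142) and -0.437 to -0.362 in 786-O, FGFR3 from 2.429 to 2.488 in 5637 and 0.23 to 0.396 in 786-O (not called at 0.287, 0.271, 0.299 and 0.23), and EZH2 from -0.396 to -0.356 in 5637 and -0.209 to -0.103 in 786-O (called at -0.209). FGFR3 in 786-O was also not called without the filter on low values (0.309), with quantile normalization (0.281) or with the replicate block (0.309). The cause was not tested. Lists past the threshold went from 8 to 0 in 5637 and from 16 to 4 in 786-O with an estimated correlation, and to 17 and 25 with fry. With the replicate block 4942 genes were called in 5637 and 6723 in 786-O. Deviations of libraries with the same number correlated at 0.083, 0.077 and 0.057 in 786-O and 0.023, -0.031 and -0.007 in 5637, so they share only a number, though in 786-O each correlated best with its own number, a hint from the data and not the design. CBX7 and FGFR3 in 786-O rest on as few as 111 and 59 reads per library, and whether depth limits them was not tested.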

Other observations

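Targets of the hypoxia factor HIF, which is constantly active in 786-O because these cells lack VHL, moved in both directions. The lipid regulator ANGPTL4 rose from 21.1 to 102 FPKM, adrenomedullin (ADM) from 56.6 to 147 FPKM, the lipid droplet protein PLIN2 from 40.1 to 72.4 FPKM and NDRG1 from 48.4 to 83.3 FPKM. The carbonic anhydrase CA12 fell from 56.8 to 24.5 FPKM and the glucose transporter SLC2A1 from 298 to 177 FPKM, while VEGFA was not called. Renal tubule genes also split, with the cadherin CDH6 (13.4 to 7.47 FPKM) lower and the brush border enzymes MME (1.81 to 3.18 FPKM) and ANPEP (28.8 to 39.2 FPKM) higher. Of the histone genes, HIST1H2BK rose from 20.3 to 51.7 FPKM and HIST2H2AC fell from 4.56 to 1.78 FPKM, although genes of DNA replication fell.

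Whether the fall of ACTB and ACTG1 in 786-O goes with a rise of targets of SRF and its cofactor MRTF was tested with a list written after TAGLN, TPM4, CALD1 and ITGA5 had been seen to rise. The hypothesis is that less actin frees MRTF, which then raises its target genes. The list leaves out ACTA2, ACTB and ACTG1 and had a median log2 change of 0.582 in 786-O, but its p-values would partly restate what had been seen, so the tests were run again without those 4 genes, a choice made after the result was seen. In 786-O, 18 of the other 25 members were higher and 4 lower (18 and 4 adjusted over the list alone, median 0.543, camera adjusted p = 7.61e-05, or an adjusted p = 0.116 with an estimated correlation). In 5637, where ACTG1 was lower by much less (log2 change -0.355) and ACTB was not lower, 16 of 24 were higher and 3 lower (16 and 3 adjusted over the list alone, median 0.177, camera adjusted p = 0.00278, or an adjusted p = 0.22 with an estimated correlation). The change was larger in 786-O (camera adjusted p = 0.0152), but not with an estimated correlation (adjusted p = 0.168), so the hypothesis stays open.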
